A study of Mus musculus with 5 samples.

How the data were processed

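The material was white adipose tissue of 10-week-old male mice on chow diet, per the labels. The protocol text of all 5 samples names C57BL/6J, but the strain field reads C57BL/7J for MWAT, C57BL/8J for NWAT and C57BL/9J for HWAT. Tissue was taken from 5 depots: subcutaneous (SWAT), epididymal (EWAT), mesenteric (MWAT), perirenal (NWAT) and peri-heart (HWAT). The mice were perfused with heparin in saline, and lymph nodes next to the depot were taken out of SWAT and MWAT. Tissue was pooled before nuclei were isolated, from 6 mice each for SWAT, EWAT and NWAT, from 10 mice for MWAT and from 20 mice for HWAT. At least 8000 nuclei per depot were loaded for droplet-based sequencing of the 3′ ends of transcripts, at 20000 or more reads per nucleus, per the labels. Each depot was thus 1 pooled library, with no replicate.

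The deposited files hold raw counts of unique molecular identifiers (UMI counts) per gene and nucleus, with no normalization. They were made with Cell Ranger 6.0.1, per the file headers, and aligned to mm10, per the submitters' processing notes. The annotation release was not stated. Each file listed 32285 genes, and every barcode in the files had 500 UMIs or more, so nuclei under that depth could not be examined.

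The marker lists, the gene lists, the rule for naming genes, the filters and most of the alternative settings were fixed before the data were examined. The thresholds for naming clusters were set after the data had been seen, and so was the rule for which list medians are printed. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. Gene positions came from GENCODE mouse release vM21 (GRCm38), matched by gene identifier for 637 of 637 genes.

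Nuclei were kept with at least 200 genes detected and at most 10% mitochondrial UMIs, which removed 149 of 76040 nuclei. Likely doublets were then taken out. Each nucleus was scored by the share of simulated doublets (sums of 2 random nuclei of its library) among its nearest neighbours on 30 components. The highest scores were removed at 0.8% per 1000 nuclei of the library, 9642 nuclei in all. The removal took 9.85% of SWAT, 14.8% of EWAT, 15.8% of MWAT, 10.2% of NWAT and 10.0% of HWAT barcodes. It took 26.3% of the nuclei that would have been pericyte-like and 6.61% of those that would have been mesothelial-like. The retained 66249 nuclei were log-normalised and reduced to 2000 variable genes and 40 principal components. They were clustered together on shared nearest neighbours (20 neighbours) by the Leiden method at resolution 1, with no batch integration.

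A cluster took the name of the marker list with the highest mean log2 fold over clusters of other classes (10 CPM added to both). The mean had to be at least 1 and lead any other class by 0.5, with 2 in 3 of the markers, and at least 3, raised 2-fold. No other class could hold more of the 10 leading genes than the class itself. Of 37 clusters, 29 were named and 8 were left unnamed. Names are written as "-like" since they rest on marker genes alone. Within a class, sub-clusters at resolution 0.5 were named by a looser rule. The mean log2 fold over the other sub-clusters had to be at least 0.5 and lead the next list by 0.25. At least 3 markers had to be raised 2-fold, without the 2 in 3 condition. The condition on markers of other classes among the 10 leading genes stayed. A sub-cluster also needed 1 of its own markers among its 10 leading genes, a condition added after the sub-clusters had been seen. It left unnamed the sub-clusters that would otherwise have been called committed preadipocyte-like. Unnamed shares are given per depot.

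Shares are percentages of retained nuclei with exact (Clopper-Pearson) 95% binomial intervals. Expression is the UMI counts summed over the nuclei of a class in a library, as CPM (counts scaled to a class total of 1e6), with exact 95% Poisson intervals. All of these intervals cover counting error only, not variation between mice, dissections or libraries. No test between depots, p-value or standard error is given, since there is no replicate. Where a class had 0 counts or nuclei, the limit is that of 3 counts, and a ratio to a depot with fewer than 3 counts was taken against 3 counts of that depot's class sum. Classes other than adipocytes and FAPs (fibro-adipogenic progenitors) were compared in libraries with at least 50 nuclei of the class, which left out SWAT mesothelial-like and HWAT pericyte-like nuclei. The share of nuclei with a UMI of a gene is given for all nuclei of the class and after thinning each nucleus to 1000 UMIs, where nuclei under that depth were left out.

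For each function list, the log2 difference of a member was its log2 CPM in a depot minus its mean log2 CPM in the other 4 depots, with 0.5 counts added. A member needed at least 20 counts summed over the libraries. The list's median was placed among 10000 random lists of the same size matched on mean expression. That percentile describes these libraries and is no test. A shift in 1 depot alone lowers the difference of the 4 others: on simulated data, a list raised by 1 in HWAT read 0.96 there and -0.25 in NWAT. The same simulation returned a median fold of 1.96 for genes doubled in HWAT adipocytes, and of 10652 genes left alone 0 had a ratio of at least 2. The simulated counts held counting error alone, from means shared by all depots. Genes were those expected at 20 counts or more in the smallest class sum. The simulation thus gives no rate of false ratios for real libraries, which also differ by mice, dissection and batch. Of 200 lists left alone, 7 to 12.5% fell outside percentiles 5 to 95, by depot. Medians are printed for lists at or beyond percentiles 1 and 99, and for the 5 lists per class with the largest medians. The lists covered thermogenic genes, lipogenesis and triglyceride synthesis, lipolysis, fatty acid uptake, secreted factors, insulin signalling, futile cycling and adipogenic transcription factors. They also covered extracellular matrix, Hox genes, other developmental regulators, interferon and inflammatory genes, complement, immediate early genes, and angiogenic factors and receptors. One listed symbol, Gpr81, was not among the genes of the files.

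The rule for named genes took, per depot, the 5 genes in adipocyte-like and FAP-like nuclei, and the 2 genes in other classes, with the largest ratio of CPM to the next highest depot. A gene needed 100 counts, a ratio of at least 2, and a CPM of at least 0.25 times the highest of any other class with 20 nuclei or more in that library, to leave out free RNA of another class. Mitochondrial, ribosomal protein, clone-named and immunoglobulin or T cell receptor segment genes were left out. For adipocytes it also took, per depot, the 3 genes with the lowest ratio to the next lowest depot, with at least 100 counts in each other depot. Of the genes it took in adipocytes, 3 are not reported here. Ucp1, Lep, Adipoq, Wt1, Hoxc10, Tbx15, Tbx5 and Xist were named whatever their values, and list members as examples.

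Alternatives covered the filters (at least 500 genes, at most 2% mitochondrial UMIs), doublet removal (none, or 1.6% per 1000 nuclei), clustering (resolution 2, each library by itself, or a class per nucleus from its own markers) and scaling (the mean over nuclei of each nucleus's CPM, or edgeR's trimmed mean of M-values, TMM). They also covered a free-RNA profile subtracted at 5%, list minimums of 1 and 100 counts, sub-clustering at resolution 1, and 200 counts for the correlations. Added after the data were seen were shares of the 6 classes alone, adipocytes without the cluster of highest mitochondrial share, and adipocytes without the sub-cluster led by Ucp1.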

Results

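Single-nucleus RNA sequencing measured the cell types and transcripts of 5 mouse white adipose depots, to build an atlas of cell types across them. The depots were SWAT (subcutaneous), EWAT (epididymal), MWAT (mesenteric), NWAT (perirenal) and HWAT (peri-heart), with 1 pooled library each. The deposited libraries held 25597948, 43855063, 29739505, 38304863 and 23313545 UMIs in 12324, 18514, 19770, 12786 and 12646 nuclei, in that order. After filtering they kept 11094, 15772, 16642, 11473 and 11268 nuclei, with medians of 1746, 2144, 1233, 2623 and 1506 UMIs. There was no replicate of any depot, so no value below has a replicate check and all intervals are 95% intervals of counting error.

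The first comparison asked how the 6 cell classes the labels name are shared out among the depots. Adipocyte-like nuclei made up more than any other class in SWAT (58.0%, 57.1 to 59.0), EWAT (54.4%, 53.6 to 55.2) and NWAT (56.3%, 55.4 to 57.2). Their share was 25.3% (24.7 to 26.0) in MWAT, where they were also the largest class by count, and 16.8% (16.1 to 17.5) in HWAT. Mesothelial-like nuclei, the lining cells of visceral surfaces, ran the other way. They were 36.7% (35.8 to 37.6) of HWAT, 24.9% (24.3 to 25.6) of MWAT, 10.1% (9.65 to 10.6) of EWAT and 7.83% (7.34 to 8.33) of NWAT, against 1 nucleus of 11094 in SWAT. Immune-like nuclei were 39.3% (38.4 to 40.2) of HWAT, 10.4% of SWAT, 9.93% of EWAT, 10.5% of NWAT and 2.45% (2.22 to 2.69) of MWAT.

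FAP-like nuclei (fibro-adipogenic progenitors, the stromal cells that include adipocyte precursors) were 9.27% (8.73 to 9.82) of SWAT, 5.29% of EWAT, 4.68% of MWAT, 5.83% of NWAT and 2.93% (2.63 to 3.26) of HWAT. Endothelial-like nuclei were 18.5% (17.8 to 19.2) of SWAT, 16.2% of EWAT, 12.9% of MWAT, 15.8% of NWAT and 3.28% (2.96 to 3.63) of HWAT. Pericyte-like nuclei were 2.24% (1.98 to 2.54) of SWAT, 1.17% of EWAT, 1.17% of MWAT, 1.44% of NWAT and 0.160% (0.0947 to 0.252) of HWAT. Clusters that could not be named held 0.829% of SWAT, 2.94% of EWAT, 7.37% of MWAT, 0.445% of NWAT and 0.745% of HWAT. MWAT also held 19.4% (18.8 to 20.0) smooth muscle-like nuclei, which entered its denominator. Over the settings tried, the pericyte-like share was 1.23 to 2.65% in SWAT, 0.526 to 1.49% in EWAT, 0 to 2.55% in MWAT, 0.915 to 1.64% in NWAT and 0 to 0.559% in HWAT. The immune-like share of MWAT was 0.873 to 4.35%, and the endothelial-like share of HWAT 0.469 to 3.61%.

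**Figure D1:**
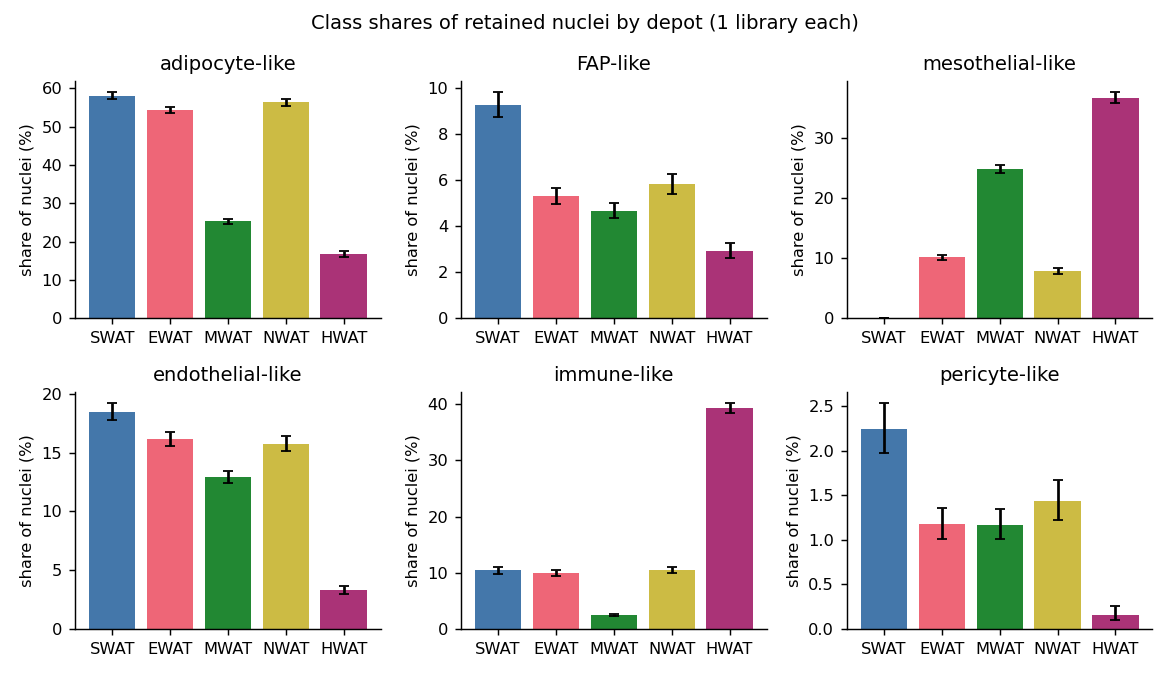
Share of retained nuclei (%) in each of 6 cell classes, 1 bar per depot library, with exact 95% binomial intervals as error bars. HWAT stands apart with 39.3% immune-like, 36.7% mesothelial-like and 16.8% adipocyte-like nuclei.

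From the highest to the lowest depot, the share ratio was 3.46 (3.28 to 3.64) for adipocyte-like nuclei, 3.16 (2.79 to 3.59) for FAP-like and 5.63 (5.04 to 6.31) for endothelial-like nuclei, each as SWAT over HWAT. It was 16.1 (14.5 to 17.8) for immune-like nuclei, HWAT over MWAT, and 14.1 (8.71 to 24.1) for pericyte-like nuclei, SWAT over HWAT, which rested on 18 HWAT nuclei. For mesothelial-like nuclei it was 4074 (731 to 160957), HWAT over SWAT, on 4138 nuclei against 1. With doublets removed at 1.6% per 1000 nuclei, the endothelial, immune and pericyte ratios were 39.9, 45.5 and 56.4. With none removed, the immune and pericyte ratios were 9.30 and 4.74. The pericyte ratio was also 6.51 at 500 genes, 46.4 with each library clustered by itself and 4.70 with the class set per nucleus. That last setting gave adipocyte-like and mesothelial-like shares of 8.67% and 20.7% in HWAT, and a mesothelial-like share of 16.1% in MWAT.

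The immune-like nuclei of HWAT were mostly lymphocytes. B cell-like nuclei were 22.5% (21.8 to 23.3) of HWAT, against 0.584% (0.453 to 0.741) of NWAT, 0.117% of SWAT, 0.0254% of EWAT and 0 of 16642 nuclei in MWAT. T or NK cell-like nuclei were 3.54% (3.21 to 3.90) of HWAT and 0.829% (0.669 to 1.02) of SWAT, and plasma cell-like nuclei were 2.36% (2.09 to 2.66) of HWAT. Macrophage- or monocyte-like nuclei differed less, with 10.9% in HWAT, 9.46% in SWAT, 9.57% in EWAT, 9.27% in NWAT and 2.40% in MWAT. Lymphatic endothelial-like nuclei were 2.48% (2.24 to 2.72) of MWAT, 1.29% of EWAT, 0.478% of SWAT, 0.106% of HWAT and 0.0872% of NWAT. The labels name lymph node removal for SWAT and MWAT alone.

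Adipocyte-like and mesothelial-like nuclei clustered by depot. Cluster 2 held 78.3% of the adipocyte-like nuclei of SWAT, cluster 0 held 90.1% of those of EWAT and cluster 4 held 81.4% of those of MWAT. Cluster 1 held 81.9% of the adipocyte-like nuclei of NWAT and cluster 12 held 94.1% of those of HWAT. Mesothelial-like nuclei of HWAT fell mostly in clusters 6 and 17, those of MWAT mostly in clusters 7 and 16, and those of EWAT and NWAT mostly in cluster 10. Cluster 7 also held 9.28% of those of EWAT and 4.34% of those of NWAT. A cluster made mostly of 1 library cannot be told from that library's own batch. FAP-like nuclei of all 5 depots shared cluster 5.

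The next comparison asked how adipocytes differ in expression between depots. HWAT adipocyte-like nuclei carried a thermogenic profile. Ucp1, the mitochondrial uncoupling protein of heat-producing fat cells, was at 267 CPM (251 to 284) there and at 2.41 CPM (1.67 to 3.37) in SWAT, a ratio of 111 (78.6 to 161). NWAT had 1 Ucp1 count, and EWAT and MWAT had 0, which allows up to 0.135 and 0.432 CPM. All 19 measured thermogenic genes were above the mean of the other depots in HWAT, 16 of them by 2-fold or more. The list's median log2 difference there was 2.50 (2.31 to 2.68), at percentile 100 of the random lists. Cidea, a lipid droplet protein, differed by 5.78 on the log2 scale, and Otop1 by 6.34, while Ppargc1a differed by 0.14. In GRCm38, Ucp1 (ENSMUSG00000031710) lies on chromosome 8 from 83290352 to 83298452.

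The thermogenic signal of HWAT lay mainly in 1 adipocyte sub-cluster led by Ucp1, Fabp3, Cidea and Cpt1b, with 270 HWAT nuclei and 1 SWAT nucleus. It was 14.3% (12.7 to 15.9) of HWAT adipocyte-like nuclei. Without it the list's median in HWAT was 0.65 and the Ucp1 ratio to SWAT was 12.9. The Ucp1 level of the other HWAT adipocyte-like nuclei was 31.2 CPM. In HWAT nuclei that should lack it, the level was 38.3 CPM in endothelial-like and 28.2 in FAP-like nuclei, 10.3 in mesothelial-like, 8.97 in B cell-like, 8.20 in T or NK cell-like, 6.51 in macrophage-like and 4.33 in plasma cell-like nuclei. A Ucp1 UMI was found in 12.9% (11.5 to 14.5) of HWAT adipocyte-like nuclei, at a median of 1898 UMIs, and in 3.07% (1.54 to 5.43) of HWAT endothelial-like nuclei, at a median of 1220 UMIs. After thinning to 1000 UMIs, which left out 291 and 118 nuclei, the shares were 9.99% (8.57 to 11.6) and 2.08% (0.680 to 4.79). In SWAT, 0.466% of adipocyte-like nuclei had a Ucp1 UMI, and 0.272% had one after thinning. Elsewhere the thermogenic median was 0.47 in SWAT, at percentile 99.99, -0.76 in NWAT, -0.56 in MWAT and -1.52 (-1.81 to -1.23) in EWAT. Part of each negative value follows from the height of HWAT: without the sub-cluster they were -0.35, -0.04 and -1.19. SWAT was then at 0.96, above the 0.65 of HWAT. At 2% mitochondrial UMIs the MWAT value was -0.29.

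Genes of fatty acid and triglyceride synthesis were low in EWAT adipocytes and high in MWAT adipocytes. The list's median was -1.04 (-1.07 to -1.02) in EWAT, at percentile 0, where 10 of 20 members were 2-fold or more below the other depots. It was 0.77 (0.74 to 0.81) in MWAT, at percentile 100, where 7 of 20 were 2-fold or more above, and 0.52 in HWAT, at percentile 99.17. Fasn, the fatty acid synthase, was at 81.9 CPM (78.2 to 85.8) in EWAT and 897 CPM (875 to 920) in MWAT, with 378 CPM in NWAT as the next lowest. The ratio of EWAT to NWAT was 0.217 (0.206 to 0.228). Elovl6, a fatty acid elongase, was at 8.93 CPM in EWAT and 96.8 CPM in MWAT, and Acly, which supplies acetyl-CoA, was at 34.2 and 287 CPM. Gpam, the first enzyme of triglyceride assembly, went the other way in EWAT, with a log2 difference of 0.52. In GRCm38, Fasn (ENSMUSG00000025153) lies on chromosome 11 from 120805846 to 120824547.

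**Figure D2:**
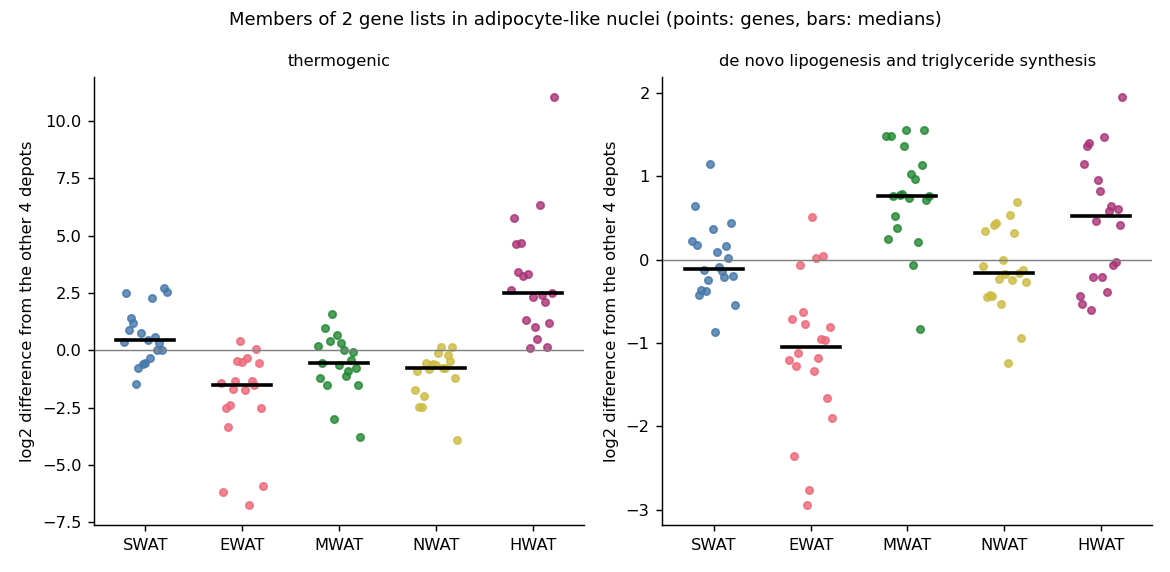
Log2 difference of each list member in a depot from its mean in the other 4 depots, in adipocyte-like nuclei, for the thermogenic list (left) and the synthesis list (right), with 1 point per gene and a bar at the median. The thermogenic median is 2.50 in HWAT and the synthesis median is -1.04 in EWAT and 0.77 in MWAT.

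Genes that mark position along the body divided the depots. Of 20 measured Hox genes, 13 were 2-fold or more lower in HWAT adipocytes. The Hox median there was -1.84 (-2.65 to -1.60), at percentile 0, or -1.39 with genes at 0 set to the limit of 3 counts. It was 0.89 in SWAT, 0.56 in EWAT and 0.48 in NWAT, each above percentile 99.9, or 0.90, 0.49 and 0.49 with the limits. Part of each positive value follows from the low value of HWAT, so these percentiles are not separate evidence for each depot. Hoxc8 had 0 counts in HWAT, which allows 0.770 CPM, against 15.7 to 77.7 CPM in the other depots, so it was at least 20.4-fold lower than in MWAT, the next lowest. Hoxc10 was at 17.5 CPM (15.3 to 19.8) in SWAT and 18.0 CPM (16.3 to 19.9) in NWAT, against 0.135 CPM in EWAT on 3 counts and 0 counts in MWAT and HWAT. Hoxa10 had the same 2 high depots, at 15.1 and 12.5 CPM.

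Among the other developmental regulators, Tbx15 was at 73.6 CPM (69.2 to 78.2) in SWAT adipocytes and at 405 CPM (377 to 435) in SWAT FAPs. NWAT followed with 14.98 and 53.4 CPM. Wt1, a regulator of visceral mesenchyme and mesothelium, had 0 counts in SWAT FAPs, which allows 1.55 CPM, against 129 CPM in EWAT, 117 in MWAT, 60.1 in NWAT and 193 (157 to 236) in HWAT. A Wt1 UMI was seen in 23.3% of HWAT FAP-like nuclei (median 1375 UMIs) and in 2.23% of HWAT endothelial-like nuclei (median 1220 UMIs), and in 14.1% and 1.67% after thinning, which left out 89 and 118. In mesothelial-like nuclei Wt1 was between 475 and 670 CPM. Tbx5, a factor of heart and forelimb, was at 40.2 CPM (35.7 to 45.2) in HWAT mesothelial-like nuclei and at least 28.0-fold higher than in NWAT, which had 0 counts. Pax3, a regulator of axial muscle and neural crest, was at 5.41 CPM (4.49 to 6.47) in NWAT adipocytes on 120 counts, with at most 1 count in each other depot. The median of these regulators in NWAT adipocytes was -0.92 (-1.12 to -0.50), or -1.20 with the limits, and members with at least 100 counts gave -0.23. With doublets left in it was -0.48. In SWAT FAPs it was 0.42, at percentile 99.51.

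**Figure D3:**
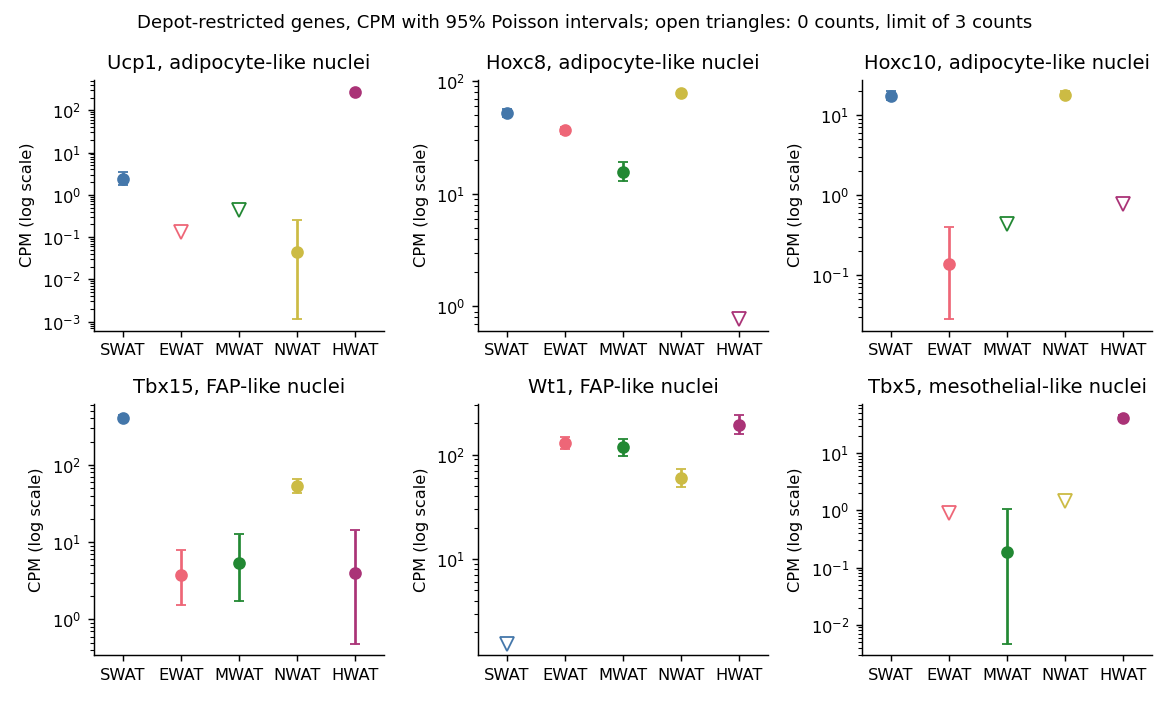
CPM on a log axis for 6 genes in the class named above each panel, 1 point per depot library, with exact 95% Poisson intervals. Open triangles mark depots with 0 counts at the limit of 3 counts, as for Hoxc8 in HWAT adipocyte-like nuclei and Wt1 in SWAT FAP-like nuclei.

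The genes most restricted to 1 depot differed in kind between adipocyte populations. EWAT had the transcription factor Sox7 at 10.6 times (8.84 to 12.8), Gnb4 at 6.28 times, and Unc119b at 4.63 times the next depot. Lypd1 was at 4.83 CPM there, on 107 counts. Sox7 and Gnb4 were higher in EWAT endothelial-like (111 CPM) and pericyte-like nuclei (114 CPM) than in adipocytes (62.5 and 31.7 CPM). H2-Q10 and Cdk6 were lowest in EWAT, at 0.105 and 0.245 of the next lowest depot. With a free-RNA profile subtracted, the ratios of Gnb4 and Cdk6 were 11.2 and 0.00994. In NWAT, Ofcc1 was 6.71 (5.41 to 8.42), Ptchd4 3.44, Arfgap2 2.76, Cd1d1 2.51 and Cdh9 2.42 times the next depot. Cdh9 was higher in NWAT FAPs (63.0 CPM) than in adipocytes (17.1 CPM). Cebpb, a transcription factor of adipogenesis, was at 0.208 (0.160 to 0.272) of the next lowest depot in NWAT, and Snrpf at 0.219.

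In SWAT adipocytes, the positional factor Shox2 was at 8.87 CPM and 8.65 times (3.29 to 32.2) HWAT. Jun was at 3.95 times (3.33 to 4.72) and Glt1d1 at 3.05 times the next depot. Shox2 and Jun were higher in SWAT FAPs, at 34.2 and 565 CPM. The urinary protein genes Mup10 and Mup17 were at 21.6 and 12.7 CPM, with at most 3 counts elsewhere, and since such paralogs share sequence, which copy was expressed is uncertain. Slpi, Nkain4 and Upk3b were lowest in SWAT, at 0.639, 0.213 and 0.142 CPM. All 3 were abundant in mesothelial-like nuclei of the other depots, at 329 CPM or more, and SWAT held 1 such nucleus. For Nkain4 the ratio to NWAT was 0.0186, or 0.102 with free RNA subtracted. In HWAT, besides Ucp1, the fatty acid binding protein Fabp3 was 58.0 (38.7 to 91.0), Itih4 32.3 (19.7 to 55.8) and Myl7 21.4 (11.9 to 42.3) times the next depot, and the noncoding Lncbate10 was at least 61.7-fold higher than in MWAT. Fabp3 at 2% mitochondrial UMIs gave 29.8, and without the sub-cluster led by Ucp1 12.8. Outside that sub-cluster HWAT adipocyte-like nuclei had Fabp3 at 44.3 CPM. That was below HWAT mesothelial-like (89.9), endothelial-like (58.5) and FAP-like nuclei (50.4), and above B cell-, T or NK cell-, macrophage- and plasma cell-like nuclei (21.3 to 34.6). Myl7, a myosin chain of heart atria, was at 84.7 CPM in HWAT endothelial-like nuclei, above its 37.0 CPM in adipocyte-like nuclei. Cpne2 was at 0.0662 of the next lowest depot in HWAT, and Mageb18 at 0.0419 (0.00858 to 0.124) on 3 counts.

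In MWAT adipocytes the rule picked 5 genes of the gut lining, Defa24 (84.0 CPM), Reg3b (72.5), Fabp2 (40.9), Zg16 (34.4) and Fabp1 (32.7). Defa24, Reg3b and Fabp2 were at least 109-fold, 94.2-fold and 53.2-fold higher than in HWAT, with 0 counts there, and at 2% mitochondrial UMIs the Defa24 and Reg3b values were 70.8 and 60.5. Defa24 is a defensin with close paralogs, so the copy is uncertain. Both Defa24 and Reg3b were also the leading genes of MWAT mesothelial-like nuclei, at 106 and 87.4 CPM, and of MWAT endothelial-like nuclei, at 113 and 105 CPM. Esrrg and Adra1a were lowest in MWAT, at 0.273 and 0.342 of the next lowest depot.

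Immediate early genes, which also respond to tissue handling, differed between libraries. In adipocytes their median was 1.52 (1.19 to 1.77) in HWAT and 0.94 in SWAT, at percentile 100 each, and -1.74 (-2.04 to -1.50) in NWAT, at percentile 0, with -0.53 in EWAT and -0.31 in MWAT (-0.0798 with free RNA subtracted). Fos was at 50.04 CPM in HWAT, 36.8 in SWAT and 3.38 in NWAT. In FAPs the median was 1.34 in SWAT, 0.60 in HWAT and -1.57 in NWAT. It was below 0 in NWAT in all 6 classes compared, from -1.74 to -1.03. The classes of EWAT and MWAT went both ways, with 0.40 and 0.33 in endothelial-like, 0.57 and 0.36 in pericyte-like and 0.33 and -0.32 in mesothelial-like nuclei. Jun in SWAT, itself a member of this list, and Cebpb in NWAT, which is not, went in the direction of the list's medians there. In HWAT adipocytes Cebpb did not, at 27.7 CPM against 179 in SWAT, 155 in MWAT and 74.0 in EWAT.

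Interferon and inflammatory genes had a median of 0.76 (0.50 to 1.12) in HWAT adipocytes, at percentile 99.96, led by Hp at 1.90 and Irf7 at 1.72, and of -0.41 in EWAT. Of the 1892 HWAT adipocyte-like nuclei, 1568 fell in a sub-cluster with the immune transcripts Igkc, Jchain, Ighm and Cxcl13 among its leading genes. The complement list was at -0.68 in NWAT adipocytes, or -0.30 as the mean of each nucleus's CPM. Angiogenic factors and receptors were at -1.12 (-1.26 to -0.89) in HWAT, with 8 of 13 2-fold or more lower. They were at 0.44 in SWAT (0.79 with free RNA subtracted). The list holds the endothelial markers Flt1, Kdr and Tek, and HWAT had 3.28% endothelial-like nuclei, against 12.9 to 18.5% elsewhere. The part of free endothelial RNA in each depot's adipocyte sums was not measured. Matrix genes were at 0.27 in SWAT, at percentile 99.84, led by Col1a1 at 1.79. That median was 0.12 without the adipocyte cluster of highest mitochondrial share, 0.18 at 2% mitochondrial UMIs, 0.0581 with doublets left in and 0.64 with free RNA subtracted. An adipocyte sub-cluster led by Col1a1, with 408 SWAT nuclei and a median of 3.00% mitochondrial UMIs, had 4 markers of other classes among its 10 leading genes. Secreted factors were at -0.23 in SWAT and -0.15 in MWAT, with Agt and Sfrp5 as their lowest members. The SWAT value was -0.34 without the cluster of highest mitochondrial share. The MWAT value ran from -0.35 with doublets left in to -0.00888 with free RNA subtracted. The lists of lipolysis, fatty acid uptake, insulin signalling, futile cycling and adipogenic transcription factors stayed between -0.36 and 0.49 in all 5 depots. Lep, the leptin gene, was at 171 CPM (158 to 184) in HWAT and 160 (155 to 165) in NWAT, against 98.8 to 105 in the other 3. Adipoq was between 1261 and 1908 CPM. The median over all genes was -0.22 in HWAT adipocytes, and with TMM scaling it was -0.0360.

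**Figure D4:**
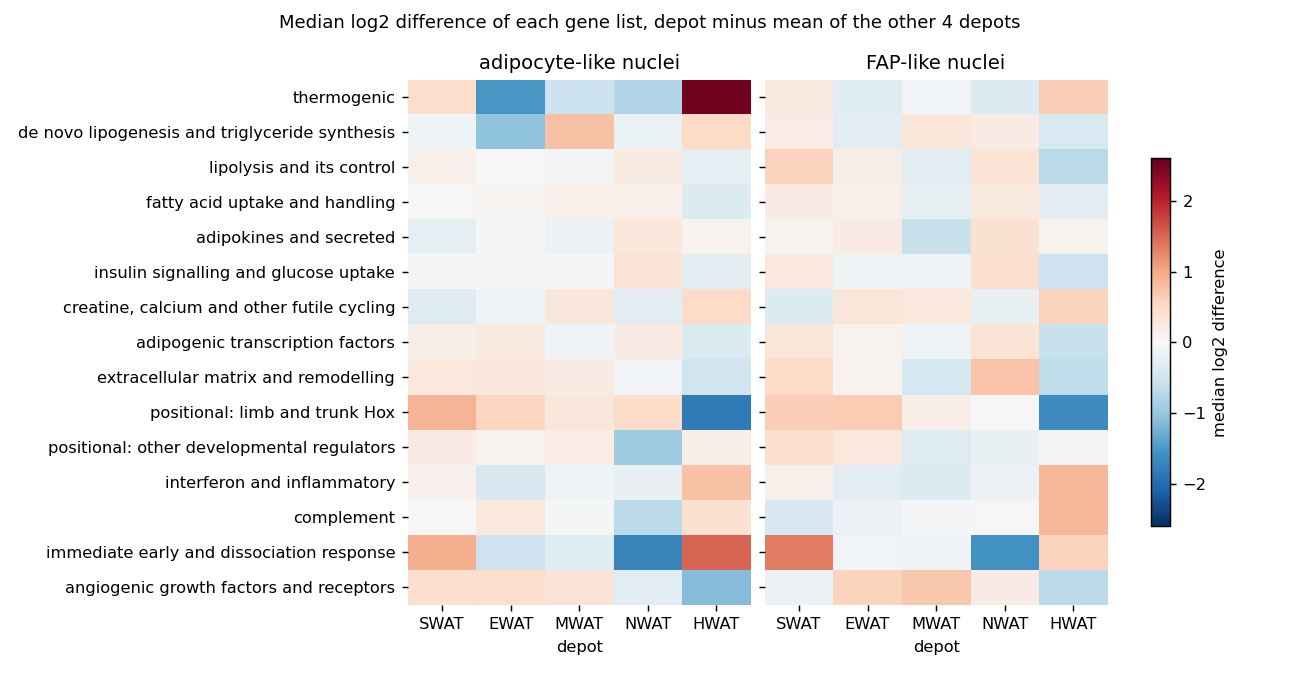
Median log2 difference of each of 15 gene lists, depot minus the mean of the other 4 depots, as a colour scale for adipocyte-like nuclei (left) and FAP-like nuclei (right), 1 column per depot library. The extremes in adipocyte-like nuclei are the thermogenic list at 2.50 and the Hox list at -1.84, both in HWAT.

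The same question was put to FAPs. Matrix genes were high in NWAT FAPs, with a median of 0.74 (0.66 to 0.81) at percentile 100 and 18 of 20 members above the other depots. They were at 0.53 in SWAT, -0.45 in MWAT (-0.68 at 2% mitochondrial UMIs) and -0.66 in HWAT. The collagen gene Col6a3 was at 858 CPM in NWAT and 115 CPM in HWAT, and Postn, a matricellular protein, at 277 and 10.1 CPM. Col1a1 was highest in SWAT, at 2765 CPM. The Hox median in HWAT FAPs was -1.64 (-2.21 to -1.34), or -0.82 with the limits. The Hox medians were 0.63 in SWAT and 0.65 in EWAT, or 0.36 and 0.47 with the limits, and the SWAT value was 0.30 with doublets left in. Part of each positive Hox value follows from the low value of HWAT. Interferon and inflammatory genes were at 0.87 (0.52 to 1.13) in HWAT, led by Cxcl1, and at -0.36 in MWAT. The complement median in HWAT was 0.87, at percentile 98.4.

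Lipolysis genes were at 0.61 in SWAT FAPs (0.42 with the limits), -0.71 in HWAT (-0.58 with the limits) and -0.27 in MWAT. Angiogenic factors and receptors were at 0.57 in EWAT and 0.70 in MWAT (0.49 and 0.46 with the limits). Secreted factors were at -0.57 in MWAT, or -0.23 with doublets left in. Synthesis genes were at 0.19 in SWAT, 0.32 in MWAT and -0.29 in EWAT, and with doublets left in at 0.0648 in SWAT and 0.61 in MWAT. Insulin signalling was at 0.28 in SWAT and 0.41 in NWAT. Adipoq, an adipocyte transcript, was at 261 CPM in SWAT, 261 in EWAT, 193 in MWAT, 431 in NWAT and 262 in HWAT FAPs, and at 431, 336, 223, 1001 and 198 CPM in endothelial-like nuclei. The remaining 4 lists, thermogenic, fatty acid uptake, futile cycling and adipogenic transcription factors, stayed between -0.58 and 0.63.

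Single genes set the FAPs apart too. NWAT FAPs were marked by Dkk2, a Wnt antagonist, at 274 CPM and 4.30 times (3.52 to 5.29) SWAT. Eya4 was at 3.83, Ppp2r2b at 3.30, Sparcl1 at 2.45 and Kcnc2 at 2.45 times the next depot. Eya4, Sparcl1 and Kcnc2 were higher in NWAT skeletal muscle-like (273 CPM), pericyte-like (535) and endothelial-like nuclei (266) than in FAPs (188, 459 and 218 CPM). SWAT FAPs were marked by Tbx15, at 7.59 times (6.13 to 9.49) NWAT, Fosb at 8.90 (3.74 to 27.7), Nat8f3 at 4.97, Jun at 4.22 and the homeobox gene Gsc at 4.07 times the next depot. Fosb and Jun are members of the immediate early list, whose median was 1.34 in SWAT FAPs. EWAT FAPs were marked by Rtl4 at 13.4 (8.58 to 21.9) and Cadps at 8.96 times the next depot. The collagen genes Col4a6 and Col6a5 were at 5.48 and 4.93 times, and Dact2 at 3.87 times. Both collagen genes were higher in EWAT mesothelial-like nuclei (367 and 251 CPM) than in EWAT FAPs (131 and 246 CPM). MWAT FAPs had Klhl29 at 2.38, Efna5 at 2.31, Wnt5a at 2.29 and Gpc3 at 2.24 times the next depot. The first 3 were at 328, 778 and 139 CPM there. They were higher in MWAT Schwann or glia-like nuclei (436 CPM), cluster 30 (1681) and mesothelial-like nuclei (159), in that order. The rule also picked Reg3b, the gut gene named above, at 112 CPM, with 105 CPM in MWAT endothelial-like and 112 CPM in MWAT macrophage-like nuclei. HWAT FAPs were marked by Olfml3 at 3.49 times. The rule also picked Tmem176b at 3.50, Csrp2 at 2.83 and Mgp at 2.65 times in HWAT FAPs, at 466, 585 and 2415 CPM. Tmem176b was higher in HWAT macrophage-like nuclei (1171 CPM), and Csrp2 and Mgp in mesothelial-like nuclei (1512 and 3667 CPM). Of 330 HWAT FAP-like nuclei, 299 fell in a sub-cluster led by Igkc, Ighm and Cxcl13. In GRCm38, Dkk2 (ENSMUSG00000028031) lies on chromosome 3 from 132085292 to 132180304, and Tbx15 (ENSMUSG00000027868) on the same chromosome from 99240381 to 99354259.

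Cxcl13, the chemokine that draws B cells, was picked in HWAT FAPs at 1721 CPM and 7.27 times NWAT, but of HWAT nuclei that should lack it, B cell-like nuclei had 1567 CPM and endothelial-like nuclei 504 CPM. A Cxcl13 UMI was seen in 59.1% of HWAT FAP-like nuclei (median 1375 UMIs) in 58.3% of B cell-like nuclei (median 1220 UMIs) and in 42.2% of endothelial-like nuclei (median 1220 UMIs). After thinning, which left out 89, 793 and 118, the shares were 53.1% (46.6 to 59.5), 52.7% (50.4 to 55.1) and 31.7% (25.8 to 38.0). HWAT macrophage-like nuclei had 6121 CPM and a share of 75.2% (median 1670 UMIs), or 66.8% (63.8 to 69.7) after thinning, which left out 217. Their ratio to NWAT macrophage-like nuclei was 46.2 (41.4 to 51.8). In GRCm38, Cxcl13 (ENSMUSG00000023078) lies on chromosome 5 from 95956951 to 95961068.

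HWAT stood furthest from the other depots across genes. The Spearman correlation across 16969 genes between adipocyte sums was highest for SWAT and EWAT (0.969) and lowest for EWAT and HWAT (0.909). Across 12835 genes in FAPs it was highest for EWAT and MWAT (0.937) and lowest for SWAT and HWAT (0.852). Genes are not replicates, and the smaller nuclei numbers of HWAT (1892 adipocyte-like, 330 FAP-like) may lower its correlations by counting noise, which was not tested. Over genes of 200 counts or more, the adipocyte values were 0.957 for SWAT with EWAT and 0.845 for EWAT with HWAT.

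Sub-classes also differed in share. Dpp4 progenitor-like FAPs, an early interstitial precursor, were 27.7% (24.3 to 31.2) of NWAT FAPs, 26.9% (24.0 to 30.1) of EWAT and 9.92% (8.16 to 11.9) of SWAT, but 1.82% (0.670 to 3.92) of HWAT and 1.41% (0.707 to 2.51) of MWAT. At sub-clustering resolution 1, the MWAT share was 3.21%. F3- or Clec11a-like FAPs were 11.2% (9.32 to 13.3) of SWAT and 2.24% of NWAT, 0.606% of HWAT, 0.240% of EWAT and 0 of 779 in MWAT, which allows up to 0.385%. Unnamed sub-clusters, most of them of 1 depot, held 78.9% of SWAT, 72.8% of EWAT, 98.6% of MWAT, 70.1% of NWAT and 97.6% of HWAT FAPs. Of 779 MWAT and 330 HWAT FAPs, 757 and 299 fell in 1 unnamed sub-cluster each. Dpp4 progenitor-like nuclei of these 2 depots may thus have gone unseparated.

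Lipid-associated macrophages, with Gpnmb, Atp6v0d2 and Mmp12 among their leading genes, were 21.9% (19.5 to 24.6) of SWAT and 17.4% (15.5 to 19.4) of EWAT macrophage-like nuclei. They were 2.82% of NWAT, 8 of 400 nuclei in MWAT and 1 of 1226 nuclei in HWAT. At resolution 1 the SWAT share was 11.7%, below the 19.7% of EWAT, and the NWAT share was 7.24%. Resident perivascular-like macrophages ranged from 55.4% in EWAT through 60.5% in SWAT, 63.0% in MWAT and 68.6% in NWAT to 71.3% in HWAT. They were 2 sub-clusters, of which 1, led by Cxcl13, Vsig4 and Marco, held 835 HWAT nuclei and 1 to 42 of each other depot, and the other held 39 HWAT nuclei and 240 to 833 of each other depot. At resolution 1 the SWAT and HWAT shares were 15.2% and 1.06%, so this sub-class has no stable size. The unnamed shares were 17.5% in SWAT, 27.2% in EWAT, 35.0% in MWAT, 28.6% in NWAT and 28.6% in HWAT.

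Arterial endothelial-like nuclei had like shares, from 14.95% (13.3 to 16.7) of NWAT to 21.9% (20.0 to 23.9) of MWAT endothelial nuclei, with 18.0% in SWAT, 19.8% in EWAT and 18.7% in HWAT. Capillary-like nuclei were 52.3% of NWAT, 48.1% of EWAT, 40.5% of SWAT, 26.2% of MWAT and 5.31% of HWAT, and venous-like nuclei 29.7% of SWAT, 22.6% of EWAT, 19.7% of NWAT, 14.4% of MWAT and 5.87% of HWAT. At resolution 1 the capillary share of EWAT was 15.05% and the venous shares of EWAT and NWAT were 12.3% and 2.50%. Unnamed sub-clusters held 11.7% of SWAT, 9.55% of EWAT, 37.5% of MWAT, 13.1% of NWAT and 70.1% of HWAT endothelial nuclei. In the joint clustering, cluster 3, led by Car4, Cyyr1 and Gpihbp1, held 36.2% of HWAT endothelial-like nuclei, lymphatic ones included. It held 49.98% of those of SWAT, 47.5% of EWAT, 23.4% of MWAT and 64.3% of NWAT. Car4 was also among the leading genes of the capillary-like sub-cluster. Capillary-like nuclei of HWAT may thus have gone unseparated, and their share of 5.31% may be too low.

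In the other classes, SWAT macrophage-like nuclei had the chemokine gene Ccl8 at 1978 CPM, 5.57 times (5.21 to 5.97) EWAT, and Jun at 3.37 times MWAT. EWAT macrophage-like nuclei had Mucl1 at 4.54 and Dcstamp, a fusion protein of giant cells and osteoclasts, at 2.73 times the next depot. NWAT had Chp2 at 2.01 times, and HWAT had Cdkn2a at 110 CPM, against 5.78 CPM in NWAT and 3.25 in EWAT, with 1 count each in SWAT and MWAT, and at least 17.7-fold higher than in MWAT. EWAT mesothelial-like nuclei had the ion channel Nalcn at 5.37 and Fst, the activin antagonist follistatin, at 4.33 times NWAT. NWAT mesothelial-like nuclei had Hoxa9 at 3.66 and Rapgef4 at 3.63 times EWAT, and HWAT had Hecw2 at 17.1 times (10.6 to 29.7) MWAT. Rapgef4 and Hecw2 were higher in endothelial-like nuclei of the same library, at 120 and 153 CPM.

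Among endothelial-like nuclei, the adhesion molecule Sele was 2.83 (1.58 to 5.58) and Cdkn1c 2.18 times the next depot in SWAT. Ccn1 was 2.24 times in EWAT, and Slco1a4, an organic anion transporter, was at least 7.45-fold higher there than in HWAT. Tnc was 3.31 and Phgdh, which opens serine synthesis, 3.11 times in NWAT. In HWAT, Ahsg was 29.2 (18.7 to 47.6) and Lsamp 8.86 times the next depot. Of 358 HWAT endothelial-like nuclei without lymphatic ones, 236 fell in a sub-cluster led by Igkc, Scgb1a1 and Jchain. It held 2 to 10 nuclei of each other depot. Among pericyte-like nuclei, Phgdh was 6.23 (3.59 to 11.7) and Fasn 4.08 times the next depot in NWAT. There Fn1 was 3.42 and Eln 3.04 times in EWAT, and Hpse2 6.77 and Inpp4b 2.04 times in MWAT. Fn1, Eln and Inpp4b were higher in another class of the same library: FAP-like (853 CPM), endothelial-like (2031) and cluster 28 nuclei (1066), in that order. No gene met the rule in SWAT pericyte-like or MWAT macrophage-like nuclei. Xist, transcribed from the inactive X of females, was at 1.35 CPM or less in adipocytes of each depot, against 83.4 to 103 CPM for the Y-linked Ddx3y and 109 to 199 CPM for Uty.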

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

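The tests of free RNA by the share of nuclei with a Ucp1 UMI and by Ucp1 over the pooled classes, of vessel walls, of the gut wall and of a lymph node were chosen only after the results were seen. Each share listed here was above the limit that a count of 0 allows and belongs to nuclei outside the 6 classes that the labels name.

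Muscle and nerve nuclei fell mainly in 1 depot each. Smooth muscle-like nuclei were 19.4% (3229 nuclei) of MWAT and Schwann or glia-like nuclei were 1.80% (299 nuclei) of MWAT, with 81 nuclei (0.730%) in SWAT, 20 in NWAT, 5 in HWAT and 2 in EWAT. Skeletal muscle-like nuclei were 1.69% (194 nuclei) of NWAT.

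Several clusters could not be named. MWAT held cluster 24, led by Rgs9, Esrrb and Tafa1, at 3.95% (658 nuclei). It also held cluster 28, led by Robo2, Pdgfra and Kcnn3, at 1.69% (281 nuclei), and cluster 30, led by Etv1, Dkk2 and Pcdh17, at 1.47% (244 nuclei). EWAT held cluster 27, led by Adcy8, Pkhd1 and Mmp7, at 2.30% (363 nuclei), and cluster 35, led by Tmem212 and the cilium motor gene Dnah12, at 0.514% (81 nuclei). SWAT held cluster 33, led by Sfrp5, Tenm2 and Ntng1, at 0.541% (60 nuclei), which also had 33 nuclei of NWAT, 17 of MWAT and 4 of HWAT. The cell cycle cluster 34, led by Top2a and Cenpf, was shared by all depots, with 32 nuclei of SWAT (0.288%), 19 of EWAT, 25 of MWAT, 18 of NWAT and 8 of HWAT. HWAT held cluster 36, led by the airway secretory genes Scgb1a1, Bpifa1 and Scgb3a1, at 0.612% (69 nuclei).

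The first pattern is Ucp1 and the thermogenic list in HWAT adipocytes. Free RNA as the whole source is argued against by the thinned share of nuclei with a Ucp1 UMI, which was 4.80 times (2.01 to 14.98) that of HWAT endothelial-like nuclei. Whether free RNA accounts for Ucp1 in the 1622 adipocyte-like nuclei outside the sub-cluster led by it cannot be told apart, because 2 tests went opposite ways. The level there was 0.814 times (0.496 to 1.41) that of endothelial-like nuclei, the highest other class, but 2.93 times (2.26 to 3.78) that of all other classes pooled. The ratio of the other thermogenic genes to cardiomyocyte markers was 42.4 times (30.6 to 58.7) higher in the sub-cluster than in endothelial-like nuclei. Thermogenic genes lead the sub-cluster, so a high ratio was partly built in and its size is no separate evidence. Heart muscle RNA is argued against only by the cardiomyocyte markers, which are not among the leading genes and did not rise likewise. They were at 134 CPM in the sub-cluster, 99.1 in other adipocyte-like and 204 in endothelial-like nuclei of HWAT. A difference between depots stays open as untested, and so does brown fat dissected with HWAT.

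The second pattern is smooth muscle and gut genes in MWAT. RNA of the gut lining was in the MWAT library, where Fabp2 had 1090 counts, with at most 1 in each other library. The marker test could not tell whether gut wall was carried with the depot. The intestinal epithelium markers were 4.98 times (4.34 to 5.73) as high over all MWAT nuclei as in HWAT, the next library, but 1.13 times (0.954 to 1.34) without Fabp2, which the naming rule had already picked in MWAT. The lower value turns on Lgr5, at 11.9 CPM in HWAT and 4.37 CPM in MWAT, while Apoa4 had 75 counts in MWAT and at most 1 in each other library. Whether the smooth muscle came from vessel walls cannot be told apart. Actg2, the enteric actin, was at 0.403 times (0.393 to 0.413) the counts of Acta2, the vascular one. That ratio alone decides nothing, since the ratio expected of gut muscle was assumed, not measured. It was 8.64 times (7.20 to 10.4) the ratio in EWAT pericyte-like nuclei. Pericytes are only a stand-in for vessel muscle, and a difference between depots stays open as untested.

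The third pattern is Cxcl13 and B cells in HWAT. Free RNA of macrophages as the only source of Cxcl13 elsewhere is argued against by its ratio to macrophage marker counts, which was 14.2 times (13.7 to 14.7) higher in mesothelial-like than in macrophage-like nuclei. It was also higher in nuclei that should lack Cxcl13, at 4.06 times in B cell-like, 3.86 in plasma cell-like, 3.34 in T or NK cell-like and 2.46 in endothelial-like nuclei. Free RNA thus need not keep the ratio of macrophage-like nuclei, and the contrast of mesothelial-like nuclei with those classes is smaller. Cxcl13 was at 3928 CPM in mesothelial cluster 6 and 349 CPM in mesothelial cluster 17. Whether a lymph node was carried with the depot cannot be told apart. There were 6.36 (5.72 to 7.09) B cell-like nuclei per T or NK cell-like nucleus, but the ratio expected of a node was assumed, not measured. A difference between depots stays open as untested.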

How the results depend on the processing

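Shares over the 6 classes alone, and medians and ratios without the adipocyte cluster of highest mitochondrial share or without the sub-cluster led by Ucp1, were tests chosen only after the results were seen, while all others were planned. Alternative ratios were run for class shares and for named genes of adipocytes and FAPs, but not for named genes of the other classes. Alternative list medians were run for adipocytes and FAPs, where the median met the rule for printing. They were not run for the other classes, nor for medians outside that rule, such as the immediate early medians of EWAT and MWAT FAPs. No list median that was run changed sign, and none of the ratios run crossed 1, under any alternative run. The median over all genes, which is near 0, did so under TMM scaling, from 0.0927 to -0.00156 in MWAT adipocytes and from -0.0506 to 0.0119 in SWAT FAPs. No ratio could be given for Upk3b in SWAT after subtraction of a free-RNA profile, nor for Lncbate10 in HWAT without the sub-cluster led by Ucp1. The highest depot was the same in all 9 settings for FAP-like (SWAT), endothelial-like (SWAT), immune-like (HWAT) and mesothelial-like nuclei (HWAT). For adipocyte-like nuclei it was SWAT in 5 and NWAT in 4 settings, and for pericyte-like nuclei SWAT in 8 and MWAT in 1. By interval, 111 of the alternative class shares moved and 129 did not. The numbers were 19 and 29 for share ratios, 52 and 408 for list medians, 28 and 440 for the ratios of all genes the naming rule took in adipocytes and FAPs, and 16 and 19 for sub-class shares. All 20 correlations moved. The cause was not tested for any moved value below, except where the setting itself shows it.

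At a minimum of 500 genes, the moved shares (%) were adipocyte 53.4 in EWAT, 26.5 in MWAT and 14.7 in HWAT, immune 2.78 in MWAT and 41.7 in HWAT, pericyte 0.344 in HWAT. Its share ratios were 3.91 for adipocyte and 6.51 for pericyte. At a maximum of 2% mitochondrial UMIs, the moved shares (%) were adipocyte 56.1 in SWAT, 24.3 in MWAT and 12.1 in HWAT, FAP 10.2 in SWAT, 6.51 in MWAT and 6.32 in NWAT, mesothelial 25.6 in MWAT and 39.6 in HWAT. Those of the other classes were immune 11.1 in SWAT and 40.9 in HWAT. Its share ratio was 4.65 for adipocyte. With doublets left in, the moved shares (%) were adipocyte 51.8 in SWAT, 49.4 in EWAT, 21.4 in MWAT, 52.0 in NWAT and 15.3 in HWAT, FAP 10.5 in SWAT, 6.30 in EWAT and 7.26 in NWAT, mesothelial 9.30 in EWAT, 21.6 in MWAT and 29.5 in HWAT. Those of the other classes were endothelial 12.3 in MWAT, immune 11.4 in SWAT, 11.2 in EWAT, 4.35 in MWAT, 11.6 in NWAT and 40.5 in HWAT, pericyte 2.65 in SWAT, 1.49 in EWAT, 1.36 in MWAT and 0.559 in HWAT. Its share ratios were 3.77 for FAP, 9.30 for immune and 4.74 for pericyte. At doublet removal of 1.6% per 1000 nuclei, the moved shares (%) were adipocyte 61.1 in SWAT, 56.0 in EWAT, 27.3 in MWAT, 57.3 in NWAT and 18.6 in HWAT, FAP 4.59 in EWAT, 3.87 in MWAT and 2.596 in HWAT, mesothelial 0 in SWAT, 27.9 in MWAT and 38.5 in HWAT. Those of the other classes were endothelial 16.9 in EWAT and 0.469 in HWAT, immune 9.09 in SWAT, 8.37 in EWAT, 0.873 in MWAT and 9.83 in NWAT, pericyte 1.69 in SWAT, 0.752 in EWAT, 0.192 in MWAT, 0.915 in NWAT and 0 in HWAT. Its share ratios were 3.28 for adipocyte, 39.9 for endothelial, 45.5 for immune and 56.4 for pericyte. Where the share of a class was 0, the limit of 3 counts applies, and the ratio was taken against it.

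At clustering resolution 2, the moved shares (%) were adipocyte 54.1 in SWAT, 23.7 in MWAT and 54.1 in NWAT, mesothelial 30.4 in HWAT, pericyte 1.25 in SWAT, 0.526 in EWAT, 0.523 in MWAT and 1.06 in NWAT. Its share ratio was 3.25 for adipocyte. With each library clustered by itself, the moved shares (%) were adipocyte 54.3 in SWAT, 52.4 in EWAT and 54.6 in NWAT, FAP 6.45 in MWAT, mesothelial 0 in SWAT and 27.1 in HWAT. Those of the other classes were pericyte 1.23 in SWAT, 0.577 in EWAT, 0 in MWAT, 1.09 in NWAT and 0 in HWAT. Its share ratios were 3.20 for adipocyte, 5.01 for endothelial and 46.4 for pericyte. With the class set per nucleus, the moved shares (%) were adipocyte 43.5 in SWAT, 45.1 in EWAT, 17.1 in MWAT, 47.7 in NWAT and 8.67 in HWAT, FAP 10.0 in SWAT, 6.18 in EWAT, 6.05 in MWAT, 6.45 in NWAT and 4.15 in HWAT, mesothelial 0 in SWAT, 7.63 in EWAT, 16.1 in MWAT, 6.44 in NWAT and 20.7 in HWAT. Those of the other classes were endothelial 16.7 in SWAT, 11.7 in MWAT and 14.4 in NWAT, immune 12.1 in SWAT, 10.5 in EWAT, 4.22 in MWAT and 45.4 in HWAT, pericyte 0.907 in EWAT, 2.55 in MWAT and 0.426 in HWAT. Its share ratios were 5.02 for adipocyte, 2.42 for FAP, 10.7 for immune and 4.70 for pericyte. Over the 6 classes alone, the moved shares (%) were adipocyte 56.0 in EWAT, 35.5 in MWAT and 57.7 in NWAT, FAP 6.55 in MWAT, mesothelial 34.9 in MWAT. Those of the other classes were endothelial 18.1 in MWAT, immune 3.42 in MWAT, pericyte 1.64 in MWAT. Its share ratio was 11.6 for immune. The 6-class shares differ by construction, since smooth muscle-like and unnamed nuclei leave the denominator.

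At a minimum of 500 genes, moved medians were adipocyte thermogenic 2.70 in HWAT. At a maximum of 2% mitochondrial UMIs, moved medians were adipocyte thermogenic -0.29 in MWAT and 2.31 in HWAT, adipocyte secreted-factor -0.25 in SWAT and -0.26 in MWAT, adipocyte matrix 0.18 in SWAT, FAP matrix -0.68 in MWAT and 0.81 in NWAT. With doublets left in, moved medians were adipocyte synthesis -1.02 in EWAT, adipocyte secreted-factor -0.35 in MWAT, adipocyte matrix 0.0581 in SWAT, adipocyte other developmental -0.48 in NWAT, FAP synthesis 0.0648 in SWAT and 0.61 in MWAT, FAP secreted-factor -0.23 in MWAT, FAP Hox 0.30 in SWAT. As means of the CPM of each nucleus, moved medians were adipocyte synthesis -1.01 in EWAT and 0.74 in MWAT, adipocyte secreted-factor -0.25 in SWAT and -0.24 in MWAT, adipocyte complement -0.30 in NWAT. Under TMM scaling, moved medians were adipocyte thermogenic 2.69 in HWAT, adipocyte synthesis -1.10 in EWAT, 0.67 in MWAT and 0.71 in HWAT, adipocyte secreted-factor -0.25 in SWAT and -0.25 in MWAT, FAP matrix 0.59 in SWAT. After subtraction of a free-RNA profile, moved medians were adipocyte thermogenic 3.04 in HWAT, adipocyte secreted-factor -0.00888 in MWAT, adipocyte matrix 0.64 in SWAT, adipocyte other developmental -1.35 in NWAT, adipocyte interferon -0.53 in EWAT, adipocyte immediate early 1.34 in SWAT and -0.0798 in MWAT, adipocyte angiogenic 0.79 in SWAT. With members of 1 count or more, moved medians were adipocyte Hox 0.32 in NWAT and -1.54 in HWAT, adipocyte other developmental -1.21 in NWAT, FAP Hox -1.10 in HWAT. With members of 100 counts or more, moved medians were adipocyte other developmental -0.23 in NWAT, adipocyte immediate early 1.34 in SWAT. Without the adipocyte cluster of highest mitochondrial share, moved medians were adipocyte secreted-factor -0.34 in SWAT and -0.29 in MWAT, adipocyte matrix 0.12 in SWAT. Without the sub-cluster led by Ucp1, moved medians were adipocyte thermogenic 0.96 in SWAT, -1.19 in EWAT, -0.0370 in MWAT, -0.35 in NWAT and 0.65 in HWAT, adipocyte secreted-factor -0.26 in SWAT and -0.21 in MWAT. Without the sub-cluster the thermogenic values changed by construction, since thermogenic genes lead it. Those other than Ucp1 were at 9961 CPM in it and at 691 CPM in the other HWAT adipocyte-like nuclei.

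At sub-clustering resolution 1, the moved shares (%) were Dpp4 progenitor 3.21 in MWAT, lipid associated 11.7 in SWAT, 19.7 in EWAT and 7.24 in NWAT, resident perivascular 15.2 in SWAT, 42.9 in EWAT, 43.2 in MWAT, 59.5 in NWAT and 1.06 in HWAT, capillary 35.9 in SWAT, 15.05 in EWAT, 24.0 in MWAT and 46.2 in NWAT, venous 23.8 in SWAT, 12.3 in EWAT and 2.50 in NWAT. Over genes of 200 counts or more, the correlations of adipocyte sums were 0.957 for SWAT with EWAT, 0.953 for SWAT with MWAT, 0.946 for SWAT with NWAT, 0.891 for SWAT with HWAT, 0.947 for EWAT with MWAT, 0.951 for EWAT with NWAT, 0.845 for EWAT with HWAT, 0.925 for MWAT with NWAT, 0.891 for MWAT with HWAT and 0.871 for NWAT with HWAT. Those of FAP sums were 0.854 for SWAT with EWAT, 0.834 for SWAT with MWAT, 0.851 for SWAT with NWAT, 0.730 for SWAT with HWAT, 0.902 for EWAT with MWAT, 0.861 for EWAT with NWAT, 0.734 for EWAT with HWAT, 0.824 for MWAT with NWAT, 0.772 for MWAT with HWAT and 0.760 for NWAT with HWAT. The order of the highest and the lowest pair was the same as at 20 counts, in both classes.

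Of the named-gene ratios reported here, 8 values for 7 genes moved by over 1.5 times. After subtraction of a free-RNA profile, Gnb4 was 11.2, Cdk6 0.00994 and Nkain4 0.102. At 2% mitochondrial UMIs, Defa24 was 70.8, Reg3b 60.5 and Fabp3 29.8. Without the sub-cluster led by Ucp1, Ucp1 was 12.9 and Fabp3 12.8.

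Depth limits the data in 3 ways. Barcodes under 500 UMIs were not in the files. HWAT had 18 pericyte-like and 330 FAP-like nuclei, and SWAT had 1 mesothelial-like nucleus. Genes with 0 counts in HWAT adipocytes could have had up to 0.770 CPM, against 0.135 CPM in EWAT and NWAT.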

Other observations

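No tests are given in this part, and its groups were picked only after the data were seen. Small populations were shared by the depots. An adipocyte sub-cluster of 53 nuclei was led by interferon-induced genes (Iigp1, Ifit3, Rsad2, Ifit1 and Usp18), with 11 nuclei from SWAT, 20 from EWAT, 6 from MWAT, 13 from NWAT and 3 from HWAT. A macrophage sub-cluster of 92 nuclei was led by cell division genes (Prc1, Kif15 and Top2a), with 19, 30, 9, 21 and 13 nuclei in that order. A sub-cluster of 104 nuclei led by Clec9a and Tlr3, genes of cross-presenting dendritic cells, had 21, 26, 9, 26 and 22 nuclei.

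Most macrophage-like nuclei of HWAT fell in a cluster with few nuclei of the other depots. Cluster 21, led by the scavenger receptor Marco, Fcna, Timd4, Vsig4 and complement C1q genes, held 905 nuclei, of which 795 came from HWAT and 73 from NWAT. Cluster 8, led by F13a1, Mrc1 and Cd209f, held 685 nuclei of SWAT, 860 of EWAT, 240 of MWAT, 765 of NWAT and 153 of HWAT. Cluster 14, led by Dock2 and Ptprc, was also shared, with 352, 639, 145, 226 and 278 nuclei in that order. A cluster mostly of 1 library cannot be told from that library's own batch.

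Immediate early genes had the same direction in all classes compared in 3 of the 5 libraries. In NWAT their median log2 difference was -1.74 in adipocytes, -1.57 in FAPs, -1.03 in mesothelial-like, -1.36 in endothelial-like, -1.26 in pericyte-like and -1.07 in macrophage-like nuclei. In HWAT it was 1.52, 0.60, 1.07, 0.93 and 0.96 in the same classes without pericyte-like nuclei. In SWAT it was 0.94, 1.34, 0.47, 0.75 and 0.79 in the same classes without mesothelial-like nuclei. In EWAT it was -0.53, -0.0622, 0.33, 0.40, 0.57 and -0.13 in the 6 classes, and in MWAT -0.31, -0.0908, -0.32, 0.33, 0.36 and -0.24.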
